A study of Mus musculus with 12 samples.

How the data were processed

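RNA immunoprecipitation followed by sequencing (RIP-seq) was measured in wild-type C57BL/6 mice, in cortex at embryonic day 12.5 and in retina at postnatal day 0. In each tissue an anti-Ythdf1 immunoprecipitate (IP), an anti-Ythdf2 IP and the input RNA were sequenced, each as 2 replicates, which gave 12 libraries in 6 groups. Per the labels, tissue was dissociated, RIP followed the EZ-Magna RIP kit, and 100 ng of RNA went into each stranded TruSeq library. Mapping with STAR 2.5, counting with HTSeq (version not given) and the genome build GRCm38 are named by the authors; the annotation release, the filters and the strand setting are not given in the sources used here. No library with an unrelated antibody is among the samples, so that the input was the only background.

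The authors deposited a table of raw read counts per gene, with 1 column per library and whole numbers throughout, and a table of FPKM for the same libraries; the gene length behind the FPKM is not stated. All tests in the report started from the counts. The table lists 52550 genes by Ensembl identifier; 52403 were matched to GENCODE M21 on GRCm38, which gave symbols, gene classes and 1-based coordinates, and 147 were left without a symbol. Library totals ran from 19530226 to 40515980 counts, and counts in protein-coding genes from 1676910 to 13621485. Those totals set the precision: 3 counts, the floor used for genes listed at 0, equal 0.0283 to 0.356 normalised CPM depending on the library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

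Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 18458 genes, 14199 of them protein-coding. Library scaling used the trimmed mean of M values (TMM); the factors ran from 0.234 to 3.17. A single edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust glmQLFit) with 1 mean per group was fitted to all 12 libraries, leaving 6 residual degrees of freedom. There were 9 comparisons: each IP against the input of its tissue, Ythdf1 IP against Ythdf2 IP in each tissue, the difference in enrichment between tissues for each antibody, and retina input against cortex input. All tests were two-sided, p was adjusted with the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The tissue difference is the retina enrichment minus the cortex enrichment. Negative values mean a higher log2 fold change over input in the cortex, which can also arise from a loss in the retina IP. Errors are standard errors (SE) of the log2 fold change or standard deviations (SD) of normalised CPM over 2 libraries. The SE was taken as the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. Where a group is listed at 0, this SE is no measure of the precision of the fitted fold. A fold against a group listed at 0 is a lower bound against a floor of 3 counts per library.

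The comparisons, the tests, the alternative analyses, the gene lists and the rule for named genes were fixed before the data were examined. The rule named genes with an adjusted p under 0.05, at least a 2-fold change, a mean of at least 5 CPM over the libraries compared, the same direction in both replicate numbers and a symbol that is not a clone or predicted name. Of these it took the 8 largest rises and falls for each IP against input, 5 and 5 for the antibody and tissue differences, and 6 and 6 for the inputs, plus the 2 higher and 2 lower members of each list with the smallest p. Ythdf1, Ythdf2, Ythdf3 and 5 genes recalled as linked to Ythdf2 in the retina were always included, and where a comparison called 5 genes or fewer these were named as well, after their values were seen. An overlapping gene with at least 50 counts was recorded for each named gene.

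In all, 35 gene lists were tested where at least 5 members passed the filter. They covered m6A readers, writers and erasers, ribosomal proteins, translation factors, the proteasome, oxidative phosphorylation, mitochondrial and small nuclear or nucleolar RNAs, histones, chromatin, zinc finger proteins, mRNA decay, signalling and axon or dendrite growth, cell cycle, stress and immediate early genes, and markers of cell types. Each list was tested with limma's camera on log CPM (prior count 2, preset correlation of 0.01), again with an estimated correlation, and with fry. The p values of camera were adjusted by Benjamini-Hochberg over the lists of a comparison. Those of fry are printed unadjusted throughout. Members past the threshold were counted over all genes tested and adjusted over the list alone. Correlations of log2 fold changes are across genes, which are not independent replicates. Because both antibodies of a tissue share the 2 input libraries, 20 data sets were simulated per tissue with IPs equal to the inputs, and the correlation and covariance they gave are printed beside the observed ones.

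The series design pairs input and IP by replicate, and a model with the replicate number as a block was an alternative. Across genes, the replicate difference of one group correlated with that of another by r from -0.0313 to 0.0582. The other alternatives fixed at that point were DESeq2 size factors, library totals alone, no filter on low counts, at least 5 CPM in 2 libraries, DESeq2's Wald test (DESeq2 1.42.0), limma-trend on log2(FPKM + 1) with at least 0.5 FPKM in 2 libraries, the same with a pseudocount of 0.1 or with no filter, only the groups of the comparison, a gene length offset (lowess with a span of 0.3 on the summed exon length) alone and with the block, a test against a fold of 1.2, mitochondrial and ribosomal RNA genes left out, and leaving out each library in turn. A GC offset alone and with the block, limma voom with library weights, fits of the 6 libraries of a tissue alone and with the block, and leaving out cortex input replicate 1 for comparisons that do not contain it were chosen after seeing the data, as was a repeat of the rule for named genes without that library. On simulated data with known changes, the 12-library model recovered 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold in the retina Ythdf1 comparison, and 0 and 1 of 100 in the cortex; a model of the retina libraries alone recovered 13 and 90 of 100, with 6 false calls among 13804 genes. Each simulation drew its counts with the spread estimated by the model's own fit. For the 12-library model this includes the cortex inputs, whose replicates differed with an SD of 2.47 on the log2 scale, against 0.746 in the retina Ythdf1 IPs. Its simulated recovery therefore does not describe the real retina libraries. No library was left out of the 12-library model. Figures were drawn with Python 3.11.15 and matplotlib.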

Results

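Transcripts recovered with antibodies against Ythdf1 and Ythdf2, 2 cytoplasmic proteins that bind N6-methyladenosine (m6A) in mRNA, were sequenced beside input RNA from mouse cortex at embryonic day 12.5 (E12.5) and retina at postnatal day 0 (P0). There were 6 groups of 2 libraries each. In the order of replicates 1 and 2, the cortex inputs held 36083984 and 33127393 counts, the cortex Ythdf1 IPs 32518602 and 23032707, and the cortex Ythdf2 IPs 28360558 and 33467121. The retina inputs held 39499994 and 36236531 counts, the retina Ythdf1 IPs 40515980 and 34033506, and the retina Ythdf2 IPs 19530226 and 24903212. Tissue and age differ together in every comparison of cortex with retina.

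Genes that lie on ribosomal RNA repeats took most counts in the IPs, from 57.9% in cortex Ythdf2 IP replicate 2 to 87.9% in retina Ythdf2 IP replicate 2. Protein-coding genes took 8.37% to 41.1% in all libraries but the library labelled cortex input replicate 1. In that library, mitochondrial ribosomal RNA took 71.0% of the counts and protein-coding genes 4.65%. Over protein-coding genes its Spearman correlation with cortex input replicate 2 was 0.585, whereas the replicates of the other 5 groups correlated at 0.908 to 0.978. The library labelled cortex input replicate 1 held 8967 counts of Camk2a, a kinase of mature excitatory synapses, against 237 in cortex input replicate 2. It held 145 counts of Nes and 45 of Mki67, genes of neural progenitors and dividing cells, against 19126 and 10931. Its profile is therefore not that of its label, and every direction drawn below from both cortex inputs rests in part on it.

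**Figure D1:**
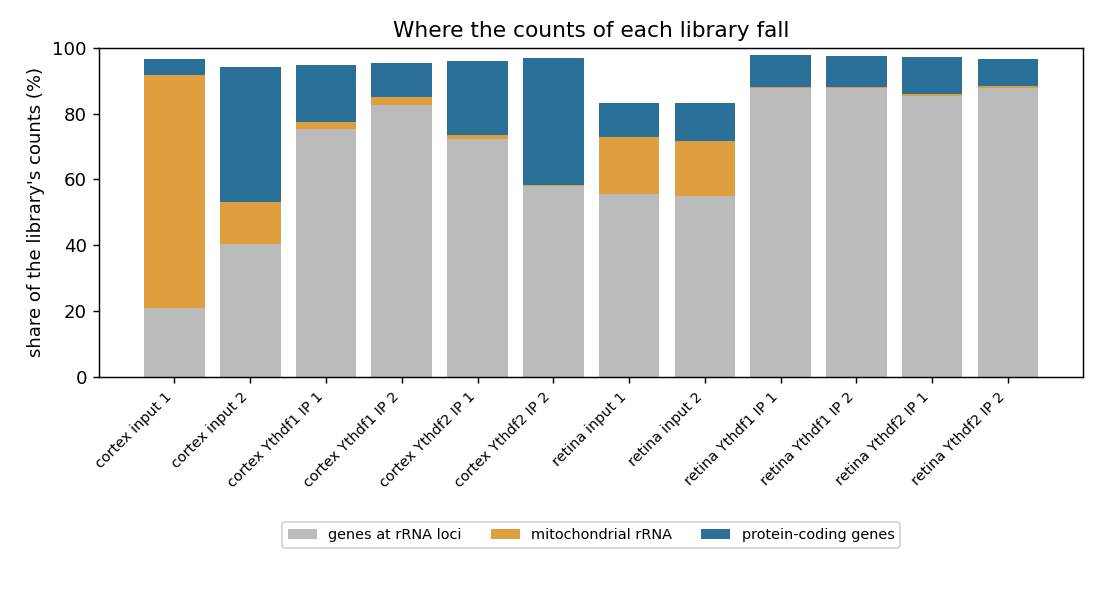
Percent of the counts of each of the 12 libraries that fell in genes on ribosomal RNA repeats, mitochondrial ribosomal RNA and protein-coding genes, with other genes not drawn. Mitochondrial ribosomal RNA took 71.0% in the library labelled cortex input replicate 1.

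**Figure D2:**
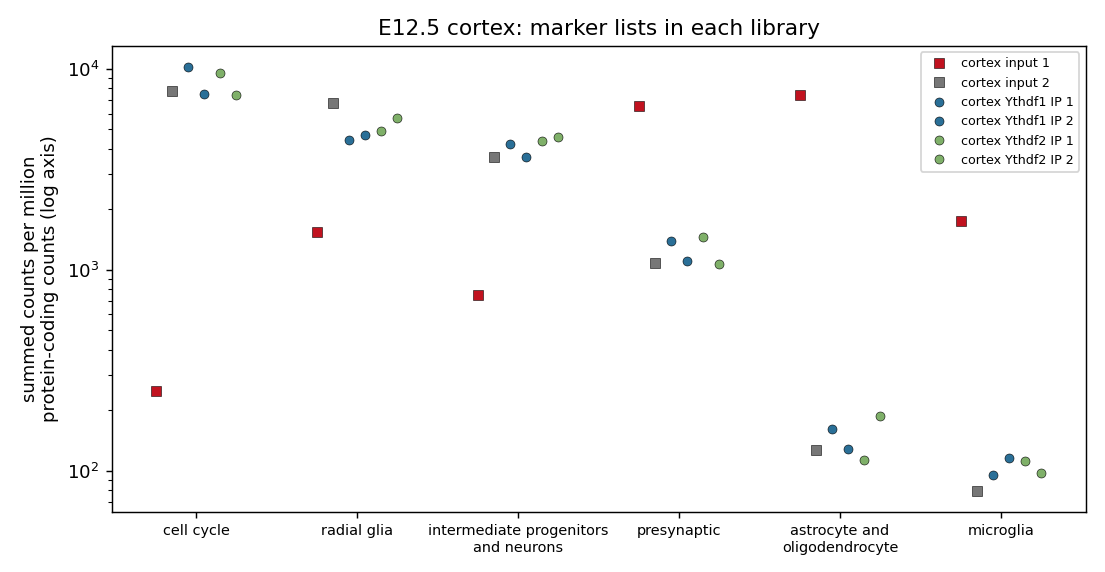
Summed counts of 6 marker lists, in CPM of the protein-coding total (log axis), in each cortex library, with the inputs as squares and the IPs as circles. In the library labelled cortex input replicate 1, the cell cycle list stood at 249 against 7387 to 10220 in the other 5 cortex libraries, and the astrocyte and oligodendrocyte list at 7442 against 113 to 187.

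The comparison of each IP with its input asks which transcripts are recovered with the antibody. In the P0 retina, 659 genes were enriched and 966 depleted in the Ythdf1 IP among 18458 genes tested, and each of these changed at least 2-fold. Plxnb2, a plexin receptor for semaphorins (chromosome 15, 89155549 to 89180788, GRCm38), rose from 25.2 ± 3.14 to 158 ± 7.25 normalised CPM (SD, n = 2), a log2 fold change of 2.65 (SE 0.50, adjusted p 0.0159). Lrrc4b, which encodes a synaptic adhesion protein (chromosome 7, 44429018 to 44463351), rose from 6.69 ± 3.03 to 61.2 ± 3.46 CPM (log2 3.19, SE 0.84, adjusted p 0.0378). Tmem115, a Golgi membrane protein (chromosome 9, 107533945 to 107538673), rose by 3.43 (SE 0.49), and the zinc finger gene Zfp12 (chromosome 5, 143235163 to 143248834) by 3.51 (SE 0.78). In the other direction, Tmsb10, whose small product binds actin monomers (chromosome 6, 72957347 to 72958748), fell from 1004 ± 536 to 26.0 ± 4.74 CPM (log2 -5.27, SE 1.00, adjusted p 0.0162). Serf1 (chromosome 13, 100108012 to 100114571) fell from 35.1 ± 9.46 to 0.589 ± 0.0316 CPM (log2 -5.89, SE 0.87, adjusted p 0.0115), and Ndufb4, a subunit of respiratory complex I (chromosome 16, 37647170 to 37654453), by 5.07 on the log2 scale (SE 0.62).

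The other genes named as most enriched in the retina Ythdf1 IP were Lars2, Urgcp, Tmem246, Pheta1 and Trim32, with log2 fold changes of 3.18 to 8.95. Of these, Lars2 differed between replicates, with 69238 and 4143 counts in the IPs against 58 and 80 in the inputs. Urgcp and Trim32 overlap other transcribed genes (Mrps24 and Ube2d-ps, and Astn2), so that their reads are uncertain in origin. The other most depleted genes were Dapl1, Pin4, Dynlrb1, Lsm5 and the processed pseudogene Ndufb4c, from -6.04 to -5.26. Reads of Ndufb4c cannot be separated with certainty from those of its parent gene.

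Transcripts of ribosomal proteins and of the respiration machinery were depleted as groups in the retina Ythdf1 IP. Of 81 cytosolic ribosomal protein genes tested, 54 were depleted (67 adjusted over the list alone; median log2 -2.47), among them Rps23 at -3.67 (SE 0.53) and Rpl32 at -3.91 (SE 0.58), the latter overlapping Snora7a. All 13 mitochondrially encoded mRNAs fell (13 over the list alone; median -6.67), and 39 of 73 nuclear genes of oxidative phosphorylation did (55 over the list alone; median -2.26). Among the latter Cox7b stood at -4.27 (SE 0.58). Depleted genes were also called in further lists. Translation factors had 6 of 28, with Eif3e at -3.26 (8 lower and 1 higher over the list alone). In summed level this list did not fall. It stood at 21700 and 17470 CPM of the protein-coding total in the retina inputs and at 23310 and 23220 in the Ythdf1 IPs. Proteasome subunits had 4 of 36 (10 over the list alone). Small nuclear and nucleolar RNAs had 17 of 83 lower and 1 higher (30 and 1 over the list alone). Camera placed each of these 6 lists below other genes, with adjusted p of 1.09e-30, 1.3e-14, 2.46e-20, 0.0136, 0.000412 and 1.6e-10. With the correlation between genes estimated from the data, the smallest adjusted p of camera over all lists was 0.323, so that no list stood apart from other genes in this IP by that version. Fry gave 0.000232, 0.000657, 0.00121, 0.113, 0.0476 and 0.0033.

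Genes of axon guidance and of signalling were among those enriched. In the axon guidance list, 6 of 40 genes were enriched in the retina Ythdf1 IP (9 over the list alone; median 1.14, camera adjusted p 1.14e-06, or 0.323 with the estimated correlation, fry 9e-04), including Plxnb2 and Plxnb1 (1.85, SE 0.43). The Wnt list had 6 enriched and 1 depleted of 35 (10 and 1 over the list alone), with the ligand gene Wnt7b at 3.09 (SE 0.56) and the transcription factor gene Tcf7l2 at -2.18 (SE 0.51). The mTOR and insulin list had 5 enriched and 1 depleted of 22 (10 and 2 over the list alone). The kinase gene Mtor rose by 2.29 (SE 0.41) and the insulin receptor gene Insr by 2.36 (SE 0.44), while Rheb, the GTPase that activates mTOR, fell by 2.71 (SE 0.54). In the Notch list, 3 of 22 were enriched (4 over the list alone), with the receptor genes Notch2 at 2.86 (SE 0.55) and Notch1 at 1.92 (SE 0.52). Camera adjusted p of these 3 lists was 0.00445, 0.00445 and 0.00697 (0.705, 0.331 and 0.786 with the estimated correlation), and fry gave 0.0236, 0.000818 and 0.0444. Of 335 zinc finger genes 24 were enriched and 3 depleted (24 and 2 over the list alone; camera adjusted p 0.000216, or 0.958 with the estimated correlation, fry 0.206). Of 32 chromatin regulators 2 were enriched, Trrap and Arid1b (2 over the list alone; camera adjusted p 0.000412, or 0.805 with the estimated correlation, fry 0.0782). In the dendrite list 3 of 38 were enriched and 2 depleted (4 and 2 over the list alone). Bdnf, the neurotrophin gene (chromosome 2, 109674700 to 109727007), was listed at 0 in both inputs and was at least 10.7-fold higher in the IP.

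Wnt7b, Tcf7l2, Notch1, Notch2, Plxnb1, Arid1b and Trp73 each overlap another transcribed gene, which leaves part of their reads uncertain. In the remaining lists at most 2 members passed in either direction. The calls were Hnrnpa2b1 among 12 m6A readers (-3.34, SE 0.82), Vamp2 among 24 presynaptic genes, Dnajb1 among 21 immediate early and heat shock genes, Cnot4 (-2.90, SE 0.47) and Cnot6l among 33 mRNA decay genes, and Fabp7 among 18 radial glial genes. They were also Reln (2.27, SE 0.49), Trp73 and Gap43 among 20 genes of intermediate progenitors and cortical neurons, with Gap43 also among 19 retinal ganglion cell genes, Kdr among 15 endothelial and Igf2 among 14 meningeal genes. Replication histones had a median of -1.09 over 67 genes tested, and cell cycle genes -0.25 over 32. In the 6 retina libraries alone 39 of 64 replication histones were lower (median -1.22). Camera adjusted p there was 5.85e-08, or 0.59 with the estimated correlation, and fry gave 0.0218. The median and the mean differed in sign for m6A readers (0.20 and -0.42), mRNA decay (0.31 and -0.02), presynaptic genes, radial glia, retinal progenitors, and amacrine and horizontal cells. By edgeR with all 12 libraries, no member was called in the lists of m6A writers and erasers, histones, cell cycle, interneurons and retinal progenitors. The same held for amacrine and horizontal cells, photoreceptors, erythroid cells, microglia, lens, pigment cells, and astrocytes and oligodendrocytes. The 6 retina libraries alone gave calls in some of these lists, among them the histones and, with 3 higher and 4 lower of 13, the m6A writers and erasers.

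The number of calls in the retina Ythdf1 IP changed when single libraries of either tissue were left out. There were 2778 enriched and 2727 depleted genes without the library labelled cortex input replicate 1, which included all 659 and 964 of the 966. Without cortex input replicate 2 there were 2062 and 3189. Leaving out retina input replicate 1 left 21 and 277, and replicate 2 left 20 and 149. With either Ythdf1 IP library left out edgeR called 0 genes, the lone IP being assumed to vary like the other groups. Leaving out a cortex IP left 159 to 259 enriched and 533 to 796 depleted, and a retina Ythdf2 IP 82 enriched and 337 or 338 depleted. With the replicate block 187 were enriched and 487 depleted. By DESeq2's Wald test the counts were 1469 and 2114, with library totals in place of TMM 0 and 0 (1278 genes at an unadjusted p under 0.05), and with limma-trend on log2(FPKM + 1) 0 and 46.

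**Figure D3:**
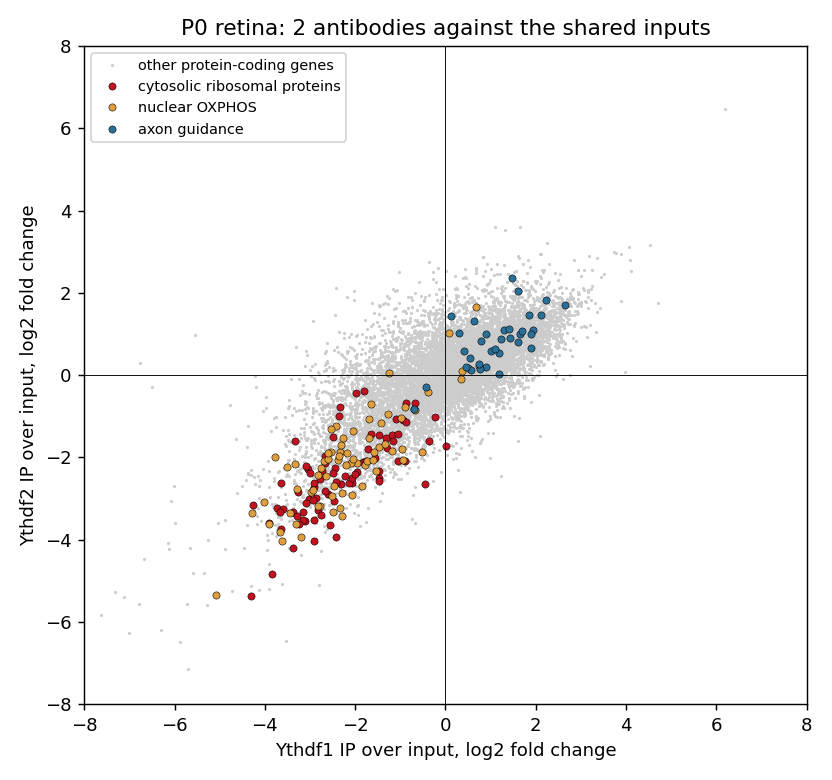
Log2 fold changes over input of the Ythdf1 IP (horizontal) and Ythdf2 IP (vertical) in P0 retina for 10595 protein-coding genes with a mean of at least 1 CPM in the retina libraries, with 3 lists in colour and 12 genes outside the axes of 8. Ribosomal protein and nuclear oxidative phosphorylation genes lie low on both axes, with medians of -2.47 and -2.26 in the Ythdf1 IP and -2.503 and -2.05 in the Ythdf2 IP.

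In the retina Ythdf2 IP, 52 genes were enriched and 325 depleted, each at least 2-fold. With the replicate block 7 genes were enriched, so that not every gene named here as enriched kept its call. Pdpk1, the kinase that activates Akt (chromosome 17, 24073680 to 24150924), rose from 7.90 ± 1.73 to 50.9 ± 3.22 CPM (SD, n = 2; log2 2.69, SE 0.50, adjusted p 0.0227). Agpat4, an acyltransferase of phospholipid synthesis (chromosome 17, 12118704 to 12219645), rose by 2.86 (SE 0.48, adjusted p 0.0163) from 1.68 ± 0.757 CPM. The transcript of the m6A demethylase Alkbh5 (chromosome 11, 60536381 to 60558512) rose from 14.9 ± 2.89 to 66.5 ± 2.84 CPM (log2 2.16, SE 0.46, adjusted p 0.036). Mib1, a ubiquitin ligase of Notch signalling (chromosome 18, 10725548 to 10818704), rose by 2.58 (SE 0.55), and Nrp2, a semaphorin co-receptor (chromosome 1, 62703285 to 62818695), by 2.36 (SE 0.49). Serf1 fell by 6.49 on the log2 scale (SE 0.92) and Tmsb10 by 5.58 (SE 1.02). Rpl36 fell from 80.5 ± 14.3 to 4.95 ± 0.427 CPM (log2 -4.02, SE 0.51, adjusted p 0.00807). Zfp46, Trim32, Atp6ap2, Fam53c and Gid4 completed the most enriched genes (2.60 to 3.60), and Pin4, Dapl1, Ndufb4c, Rpl35, Ndufb4 and Usmg5 the most depleted (-7.15 to -5.22).

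Depleted groups comprised 44 of 81 ribosomal protein genes (72 over the list alone; median -2.503), 7 of 13 mitochondrially encoded mRNAs (13 over the list alone; median -5.28) and 20 of 73 nuclear oxidative phosphorylation genes (57 lower and 2 higher over the list alone; median -2.05). Camera adjusted p was 5.32e-45, 5.54e-14 and 8.31e-25, and fry gave 0.000162, 0.00312 and 0.00175. With the estimated correlation the smallest adjusted p over all lists was 0.228. Of 83 small nuclear and nucleolar RNAs 12 were depleted (25 lower and 2 higher over the list alone). Of the proteasome and translation factor lists, 0 of 36 and 1 of 28 genes were depleted (7 and 5 over the list alone). Rnu3b4, a U3 RNA that 2 overlapping records share, was listed at 0 in both Ythdf2 IPs and was at least 1170-fold lower. The axon guidance list had 1 enriched gene, Nrp2 (median 0.95 over 40, camera adjusted p 2.62e-06, or 0.228 with the estimated correlation, fry 0.00533). There were 1180 enriched and 1550 depleted genes without the library labelled cortex input replicate 1, which included all 52 and 324 of the 325. They were 896 and 1647 without cortex input replicate 2. Without retina input replicate 1 edgeR called 0 genes, without replicate 2 it called 5 and 68, and with either Ythdf2 IP left out 0. Leaving out a cortex IP left 7 to 10 and 156 to 238, and a retina Ythdf1 IP 0 and 74 or 78. With the replicate block 7 were enriched and 176 depleted, with DESeq2's Wald test 522 and 1057, and with library totals in place of TMM 0 and 2.

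**Figure D4:**
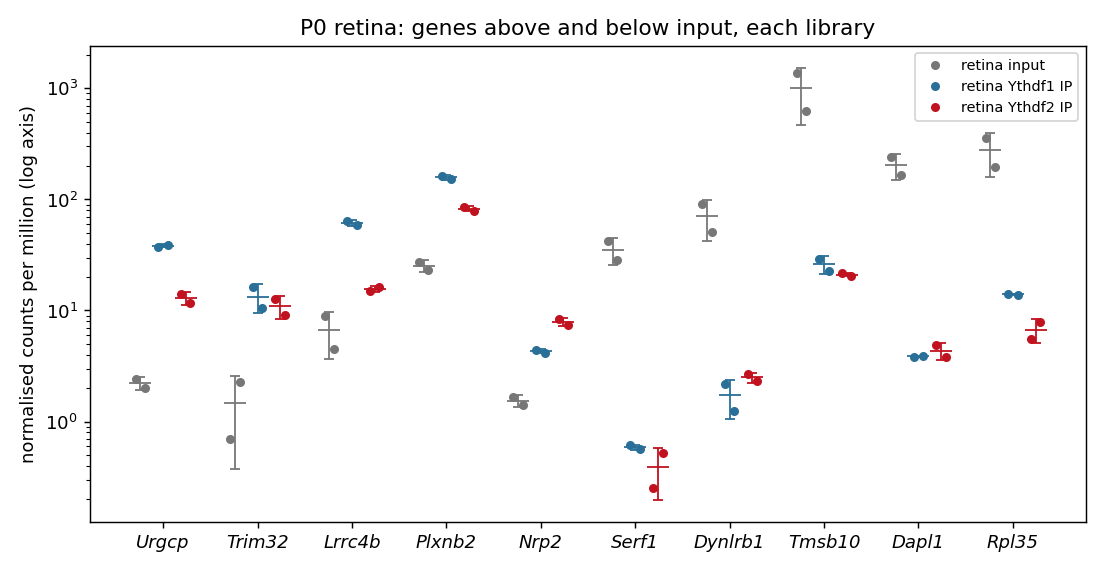
Normalised CPM (log axis) of 10 named genes in the 6 retina libraries, where points are libraries, horizontal bars the mean and whiskers 1 SD of 2 replicates. Plxnb2 stands at 25.2 in the input and 158 in the Ythdf1 IP, and Tmsb10 at 1004 and 26.0.

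The direct comparison of the antibodies asks whether they recovered different transcripts. In the retina, edgeR called 0 genes between the Ythdf1 and Ythdf2 IPs, with 2211 at an unadjusted p under 0.05, whereas DESeq2's Wald test called 663 and limma-trend on log2(FPKM + 1) called 0. Leaving out the library labelled cortex input replicate 1, which is in neither group, gave 434 genes higher in the Ythdf1 IP and 786 lower. Leaving out cortex input replicate 2 gave 281 and 968, and the 6 retina libraries alone gave 369 and 944. Strn, which encodes a scaffold of protein phosphatase 2A (chromosome 17, 78649913 to 78737196), stood at 6.82 ± 0.503 CPM in the Ythdf1 IP and 27.0 ± 4.47 in the Ythdf2 IP (log2 -1.98, SE 0.60, adjusted p 0.24). Its adjusted p was 0.0217 without the library labelled cortex input replicate 1 and ran from 1.55e-06 to 1 over all alternatives. Over 18458 genes the log2 fold changes of the 2 antibodies correlated at r = 0.587 (Spearman 0.642). In all, 24 genes were enriched in both, against 1.86 for independent calls, and 278 depleted in both, against 17. Part of this excess may come from the shared inputs, which cannot be divided with 2 libraries. In the 6 retina libraries alone r was 0.690, while IPs simulated equal to the inputs gave 0.682 (0.668 to 0.701). The covariance was 1.69 against 0.258 simulated. There, 953 and 1285 genes were called higher or lower in both against 238 and 312 for independent calls. The simulated IPs gave 0 such genes, but also 0 calls for either antibody. They therefore do not measure how far the shared inputs raise the number of joint calls.

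In the E12.5 cortex, edgeR called Zbtb9 alone in the Ythdf1 IP and Zbtb9 and Hic2 in the Ythdf2 IP, all enriched. It called 0 depleted genes in either, where 2884 and 3562 genes had an unadjusted p under 0.05. Zbtb9, a zinc finger gene (chromosome 17, 26973167 to 27008376), had 0 counts in both cortex inputs against 340 and 114 in the Ythdf1 IPs and 360 and 1160 in the Ythdf2 IPs (adjusted p 0.00162 and 0.00121). It was named because so few genes were called. Part of its reads is uncertain in origin: summed with Ggnbp1, which starts downstream, it was not called (log2 1.15 and 1.40, adjusted p 0.307 and 0.172). Hic2, a transcriptional repressor gene (chromosome 16, 17233572 to 17263430), rose in the Ythdf2 IP from 0.138 ± 0.196 to 12.6 ± 5.15 CPM (SD, n = 2; log2 5.89, SE 0.72, adjusted p 0.0342). With the replicate block only Zbtb9 was called in each IP, and the adjusted p of Hic2 was 0.0771 (2.93e-13 to 0.692 over all alternatives). DESeq2's Wald test called 436 enriched and 912 depleted genes for Ythdf1 and 753 and 1461 for Ythdf2, and limma-trend on log2(FPKM + 1) called 0 and 0, and 15 and 5. A model of the 6 cortex libraries alone called 0 genes for either antibody, with 1539 and 1983 at an unadjusted p under 0.05.

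These counts rest on the cortex inputs. Leaving out the library labelled cortex input replicate 1 leaves a single cortex input, which is assumed to vary like the other groups. Then 314 genes were enriched and 441 depleted in the Ythdf1 IP and 503 and 1014 in the Ythdf2 IP. Without cortex input replicate 2, whose remaining partner contradicts its label, the counts were 2796 and 2215, and 3250 and 2371. Leaving out any other library left 1 or 2 enriched genes for Ythdf1 and 1 to 3 for Ythdf2. The following values use cortex input replicate 2 only. Apc2, a neuronal relative of the Wnt regulator Apc (chromosome 10, 80295977 to 80318263), rose from 7.53 CPM to 82.9 ± 31.9 in the Ythdf1 IP (log2 3.46, SE 0.53, adjusted p 0.00307) and to 108 ± 40.5 in the Ythdf2 IP (log2 3.84, SE 0.54, adjusted p 0.00102). Snrpf, a core protein of spliceosomal particles (chromosome 10, 93583029 to 93589706), fell from 79.1 to 8.52 ± 4.19 CPM (log2 -3.23, SE 0.41) and to 3.77 ± 0.412 (log2 -4.39, SE 0.42). Magoh, a core protein of the exon junction complex, fell by 4.09 (SE 0.45) in the Ythdf2 IP, and Cyb5r3 fell by 4.02 and 3.62. Zfp629 rose by 5.03 and 5.69, and Hic2 rose in both, by 5.49 with Ythdf2. The other named genes for Ythdf1 were Zbtb9, Nnat, Hist1h4j, Hist1h4f and Hist1h4k above input and Hmgb1-ps2, Rpl17-ps3, Ssbp1, Lhx5, Cep19 and Psmc1 below. For Ythdf2 they were Zbtb9, Kbtbd11, Zfp628, Kcna3 and Nyap1 above and Igf2, Hmgb1-ps2, Ssbp1, Mrpl18 and Snrpd3 below. Reads of the pseudogenes, of the near-identical histone genes, and of Apc2, Snrpf, Snrpd3, Mrpl18, Nnat and Igf2, which overlap other transcribed genes, are uncertain in origin.

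Replication histone genes stood out in the cortex Ythdf1 IP. With all libraries 51 of 67 were enriched over the list alone and 0 over all genes (median 2.88). When the library labelled cortex input replicate 1 was left out the count was 24 of 68 over all genes and 47 over the list alone (median 2.13, camera adjusted p 2.47e-24, or 0.489 with the estimated correlation, fry 0.00953). In the Ythdf2 IP without that library, 5 lists were below the input. They were ribosomal proteins (30 of 81 depleted; 48 over the list alone; median -1.14), nuclear oxidative phosphorylation genes (28 of 74; 49 over the list alone; median -1.41), proteasome subunits (16 of 37; 23 over the list alone; median -1.495), mitochondrially encoded mRNAs (9 of 13; 12 over the list alone; median -2.93) and translation factors (7 of 28; 11 over the list alone; median -1.01). Camera adjusted p was 1.62e-16, 1.62e-16, 5.24e-12, 1.16e-09 and 2.22e-05, and fry gave 0.0176, 0.0142, 0.00133, 0.00823 and 0.00011. With the estimated correlation the smallest adjusted p over all lists was 0.489 for Ythdf1 and 0.177 for Ythdf2. In the Ythdf1 IP without the library labelled cortex input replicate 1, ribosomal proteins had a median of 0.02. The Ythdf1 replicates lay on opposite sides of the remaining input in summed level. They stood at 17710 and 30100 CPM of the protein-coding total, against 26130 in cortex input replicate 2. With all libraries, presynaptic genes, microglial genes and glial genes were lower over the list alone in the Ythdf1 IP (15 of 24, 9 of 13 and 9 of 11). That rests on the library labelled cortex input replicate 1, since without it the presynaptic list had 1 call, which was higher, and at most 1 member passed in the others.

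The cortex IPs share their inputs too. There r between the antibodies was 0.783 over 18458 genes. In the 6 cortex libraries alone it was 0.792, with a covariance of 2.19. Simulated IPs equal to the inputs gave 0.883 (0.874 to 0.892), with a covariance of 1.75. The simulated spread of the inputs came from both cortex inputs, including the library labelled cortex input replicate 1, whose profile is not that of its label. The simulation therefore cannot tell whether the antibodies agree more or less than shared inputs alone would give. Between the cortex Ythdf1 and Ythdf2 IPs edgeR called 0 genes, with 739 at an unadjusted p under 0.05; DESeq2's Wald test called 72 and limma-trend on log2(FPKM + 1) called 3. Without cortex input replicate 2, 104 genes were higher in the Ythdf1 IP and 8 in the Ythdf2 IP, and with the library labelled cortex input replicate 1 left out the counts were 136 and 7. Igf2, the fetal growth factor gene (chromosome 7, 142650766 to 142666816), stood in the latter model at 364 ± 99.4 CPM in the Ythdf1 IP and 13.0 ± 4.74 in the Ythdf2 IP (log2 4.81, SE 0.41, adjusted p 5.94e-05), though it overlaps Igf2os as Gapdh overlaps Iffo1. The glycolytic gene Gapdh was higher by 3.10 (SE 0.44) and the ubiquitin gene Ubb by 2.99 (SE 0.38), and Zfp407 was lower by a log2 value of -2.62 (SE 0.36). Of 81 ribosomal protein genes 11 were higher in the Ythdf1 IP (73 over the list alone; median 1.13), and of 68 histone genes 25 (50 over the list alone; median 1.65). Camera adjusted p of these lists was 8.66e-39 and 5.61e-35 and fry gave 0.00839 and 0.00728, while the smallest adjusted p with the estimated correlation was 0.232. Other lists had a median above 0 too, among them nuclear oxidative phosphorylation genes (6 of 74, median 1.26), mitochondrially encoded mRNAs (4 of 13, median 1.79), erythroid genes (0 of 12, median 1.499) and meningeal genes (1 of 14, median 0.67). Over the list alone these had 53 higher and 1 lower, 8, 7 and 3 higher, and Igf2 belongs to the last. Their camera adjusted p was 7.44e-29, 3.87e-13, 2.63e-05 and 8.72e-06, each 0.232 with the estimated correlation, and fry gave 0.0159, 0.0142, 0.00898 and 0.00457.

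Whether enrichment itself depends on the tissue was asked next. In the model of all libraries it differed for Zbtb9 alone with Ythdf1 and for 6 genes with Ythdf2. These were Zbtb9 and the small RNAs Gm24305, Gm22620, Gm25360, Rnu1b1 and Rnu1b2, all with a higher log2 fold change over input in the cortex. In the cortex Ythdf2 IP Gm22620 stood at -0.18 and the other small RNAs at 1.84 to 2.95, none of them called there. In the retina Ythdf2 IP those others fell by log2 values of -5.03 to -3.68. Gm22620 had 0 counts in both retina Ythdf2 IPs against 975 and 534 in the inputs. With the replicate block 0 genes differed with Ythdf1, and Zbtb9 and Gm24305 did with Ythdf2. Summed with Ggnbp1, Zbtb9 was not called with either antibody (adjusted p 0.881 and 0.589). DESeq2's Wald test called 1149 and 451 genes, limma-trend on log2(FPKM + 1) called 0 and 0, and 3064 and 2080 had an unadjusted p under 0.05. Leaving out 1 of the 10 other libraries gave 0 to 5 and 0 to 8 genes, and leaving out cortex input replicate 2 gave 5103 and 4315. When the library labelled cortex input replicate 1 was left out the counts were 714 (226 more enriched in retina) and 186 (90). Ngfr, a neurotrophin receptor gene (chromosome 11, 95568818 to 95587735), was then more enriched in the retina Ythdf1 IP by 3.97 (SE 0.90, adjusted p 0.0293). It stood in retina at 16.6 ± 11.8 CPM in the input and 65.4 ± 1.76 in the IP, and in cortex at 5.51 in the input and 1.35 ± 0.427 in the IP. Zfp407 differed by 5.03 (SE 0.55) with Ythdf1, and Pon2 by 4.15 (SE 0.56) and Agpat4 by 3.83 (SE 0.58) with Ythdf2. Ribosomal protein genes were less enriched in retina than in cortex with Ythdf1 (46 of 81; 60 over the list alone; median -2.52) and with Ythdf2 (9 of 81; 37 lower and 1 higher over the list alone; median -1.17). Replication histones were too (39 of 68 and 10 of 68; medians -3.18 and -2.35; 54 and 46 over the list alone). Camera adjusted p was 2.77e-29, 1.49e-11, 3.09e-28 and 5.26e-18 in that order, fry gave 0.00442, 0.0543, 0.00376 and 0.0194, and no list passed with the estimated correlation. Other named genes such as Prdm13, Dmrta2, Six6 and Dapl1 rest on counts near 0 in 1 of the tissues. With all libraries the log2 fold changes of an antibody correlated between tissues, which share no library, at r = 0.0986 for Ythdf1 and 0.141 for Ythdf2 (Spearman 0.179 and 0.225). They correlated at 0.281 and 0.390 over the 6164 genes with a mean of at least 5 CPM.

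The inputs were compared to describe the RNA the IPs started from. Of 18458 genes 648 were higher in retina and 740 in cortex. Crx, which is needed for photoreceptor fate (chromosome 7, 15865947 to 15879968), had 1094 and 1044 counts against 0 in both cortex inputs (n = 2), at least 192-fold higher. Pdc, Foxn4, Nr2e3, Opn1sw and the Rax antisense gene Raxos1 were at least 55.3-fold to 165-fold higher, with Opn1sw and Raxos1 overlapping other genes. In cortex, Emx2, a patterning gene of the dorsal forebrain (chromosome 19, 59458372 to 59465357), was higher (log2 -9.60, SE 1.53, adjusted p 0.00944), though it overlaps Emx2os. Neurod6, a gene of cortical excitatory neurons (chromosome 6, 55677822 to 55681263), was at least 224-fold higher. The neuropilin genes Nrp1 and Nrp2 were lower in retina by -2.90 (SE 0.49) and -3.64 (SE 0.51), and cyclins exchanged, with Ccnd1 at 4.66 (SE 0.82) and Ccnd2 at -6.51 (SE 1.09). Mal, Fam107a, Aqp4 and Rasgrf1, at least 654-fold, 507-fold, 287-fold and 194-fold higher in cortex, rest on the library labelled cortex input replicate 1, and none of the 4 was called without it. Hbb-bt, at least 409-fold higher, stood at 77.6 CPM in that library and 8.30 in cortex input replicate 2, and was at least 80.4-fold higher without that library. There the bounds were 1110-fold for Crx, 318-fold to 953-fold for the 5 genes after it and 337-fold for Neurod6.

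Over the lists, photoreceptor genes (9 of 17 higher in retina; 14 over the list alone; median 5.74, or 4.98 with genes at 0 set at their bound) and erythroid genes (10 of 12 lower; 11 lower and 1 higher over the list alone; median -8.83, bounded -7.93) differed most. Camera with the estimated correlation also set them apart, at an adjusted p of 0.0153 each, and no other list. Retinal progenitor genes (6 of 16 higher; 10 over the list alone) and retinal ganglion cell genes (6 of 19; 9 higher and 1 lower over the list alone) were higher, endothelial genes lower (11 of 15; 12 over the list alone), and 33 of 81 ribosomal protein genes higher (53 over the list alone; median 1.63). Without the library labelled cortex input replicate 1 the endothelial list had 10 genes lower and 1 higher. In that library its summed level was 1527 CPM of the protein-coding total, against 326 in cortex input replicate 2 and 302 and 282 in the retina inputs. Leaving out the library labelled cortex input replicate 1 changed the fitted sign of 4 genes called in the model of all libraries, whether or not they were still called. Leaving out cortex input replicate 2 changed the sign of 13 such genes. The numbers of genes higher in retina and in cortex also changed when a library was left out. Without retina input replicate 1 there were 100 and 35, and without replicate 2 there were 228 and 189. Leaving out an IP gave 292 to 459 and 347 to 418. With library totals in place of TMM 76 genes were higher and 283 lower in retina, with the replicate block 403 and 404, and with limma-trend on log2(FPKM + 1) 49 and 25.

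Among the transcripts of the readers themselves, Ythdf1 (chromosome 2, 180904377 to 180920949) had a log2 fold change of 0.96 (SE 0.44, adjusted p 0.182) in the retina Ythdf1 IP, Ythdf2 of 1.09 (SE 0.67, adjusted p 0.318) and Ythdf3 of 0.43 (SE 0.59, adjusted p 0.697). By edgeR with all libraries none of these differences was called. Over all alternatives the adjusted p ran from 0.026 (without the library labelled cortex input replicate 1) to 1 for Ythdf1, from 0.0432 to 1 for Ythdf2 and from 0.0245 to 1 for Ythdf3. In the retina Ythdf2 IP the values were 0.66, 0.35 and 0.33, in the cortex Ythdf1 IP 0.68, 0.57 and 1.09, and in the cortex Ythdf2 IP 0.90, 0.91 and 1.64, none of them called by that model. Without cortex input replicate 2, Ythdf2 was called in the cortex Ythdf1 IP and Ythdf1, Ythdf2 and Ythdf3 in the cortex Ythdf2 IP. The only cortex input left there is the library labelled cortex input replicate 1, whose profile is not that of its label. These calls are therefore no evidence of enrichment. The m6A reader list stood at 1224 CPM of the protein-coding total in that library and at 5245 in cortex input replicate 2. In the cortex IPs it stood at 4237 to 4792. Over all alternatives the adjusted p ran up to 0.981 for each gene in the cortex Ythdf2 IP. Of the 5 genes recalled as linked to Ythdf2 in the retina, Ubr4, a large ubiquitin ligase gene (chromosome 4, 139352609 to 139489588), was enriched in the retina Ythdf1 IP (log2 2.41, SE 0.48, adjusted p 0.019) from 26.4 ± 6.42 to 140 ± 6.55 CPM, though it overlaps Emc1. With Ythdf2 in retina Ubr4 reached 1.58 (adjusted p 0.114), Strn 1.90, Hspa12a 1.76, Kalrn 1.03 and Islr2 0.99, and adjusted over the list alone 3 of the 5 were enriched (camera adjusted p 0.00199, or 0.228 with the estimated correlation; fry 0.000402). With the library labelled cortex input replicate 1 left out, 4 of the 5 were enriched in each retina IP over all genes, with an adjusted p of 0.0138 for Strn in the Ythdf2 IP (0.00597 to 1 over all alternatives).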

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

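The tests of library scaling, of RNA from more mature brain, of an exchange with a retina library, of Ggnbp1, and of oxidative phosphorylation genes as a separate list in this part were chosen after the result was seen, as were the GC offset, the values at the floor and every value without the library labelled cortex input replicate 1.

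The difference in enrichment between tissues, tested directly, singled out Zbtb9 with both antibodies and 5 small RNAs with Ythdf2. For Zbtb9 the retina minus cortex difference was -10.15 with Ythdf1 (SE 1.03, adjusted p 0.0178; range over the alternatives 5.81e-09 to 1) and -11.08 with Ythdf2 (SE 1.02, adjusted p 0.00686; range 4.41e-11 to 0.486), with 4 of 4 cortex IPs above both cortex inputs. These fitted differences are no bounds, since both cortex inputs were at 0; with the floor of 3 counts per library in their place they were -4.21 and -5.15. The small RNAs were Gm24305 at -6.87 (SE 0.80, adjusted p 0.02), Gm22620 at -12.83 (SE 1.52, adjusted p 0.03), Gm25360 at -6.63 (SE 0.89, adjusted p 0.0439), and the U1 genes Rnu1b2 at -7.23 (SE 1.02, adjusted p 0.044) and Rnu1b1 at -7.24 (SE 1.02, adjusted p 0.044). In each of the 5, both retina Ythdf2 IPs lay below both retina inputs. The fitted value of Gm22620 is no bound either, since it was listed at 0 in both retina Ythdf2 IPs against 975 and 534 counts in the retina inputs, and at the floor it was -7.84. With the replicate block, which follows the pairing of the design, Zbtb9 with Ythdf1 (adjusted p 0.113) and 4 of the 5 small RNAs (0.057 to 0.086) were no longer called, and Zbtb9 with Ythdf2 and Gm24305 were (both 0.0463). Over all alternatives the adjusted p of the small RNAs ran from 2.6e-14 to 0.53 for Gm24305, 2.84e-11 to 0.368 for Gm22620, 8.59e-14 to 1 for Gm25360 and 8.68e-13 to 1 for the U1 genes. Rnu1b1 and Rnu1b2 differ by at most 2 counts in any library and are therefore read as a single measurement. The cortex side rests in part on the library labelled cortex input replicate 1, and without it the differences of the small RNAs ran from -12.53 to -6.16. No biological explanation of these small RNAs was tested.

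Zbtb9 had 0 counts in both cortex inputs and 143 or 169 in the retina inputs. Reads assigned to Ggnbp1, which starts downstream on the same strand, are a candidate cause. An overlapping Ggnbp1 record of the annotation is absent from the count table. That absence holds for every library, so it does not by itself explain why only the cortex inputs were at 0. Ggnbp1 held 14 and 483 counts in the cortex inputs, all of the sum of both genes, against 4.92% to 16.8% of the sum in the IPs. With both genes summed, the larger tissue difference was -1.11 (SE 0.72, adjusted p 0.589), and enrichment in cortex was 1.15 (SE 0.51, adjusted p 0.307) and 1.40 (SE 0.52, adjusted p 0.172). A difference in the transcripts made at this locus in the E12.5 cortex stays open as untested.

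The library labelled cortex input replicate 1 correlated with the other cortex libraries at 0.56 to 0.598 over protein-coding genes, and thinning cortex input replicate 2 to the same protein-coding total still gave 0.878 to 0.911 with the IPs, which argues against few reads as the cause. Its photoreceptor list stood at 37.6 CPM of the protein-coding total against 1903 to 2944 in the retina libraries, which argues against an exchange with one of them. RNA of more mature brain, in place of or mixed into the labelled tissue, is a candidate source that stays open: the astrocyte and oligodendrocyte list stood 39.8-fold above the highest other cortex library (3 of its 11 genes were seen in all 5 other cortex libraries and 2 are in another list), with Mbp at 2380 and Mal at 689 CPM of that total. Presynaptic genes stood 4.49-fold and microglial genes 15.3-fold above, and cell cycle genes 29.6-fold below the lowest. No sort or gate is stated, and a different age or region of the sample stays open as untested.

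Ribosomal protein and nuclear oxidative phosphorylation transcripts were below input in both retina IPs. With a gene length offset and the replicate block the ribosomal median in the Ythdf1 IP was -1.86 (quartiles -2.47 and -1.04, 28 of 81 depleted). With the block alone it was -2.46 (42 depleted), and a GC offset with the block gave -2.73 (58). The list lay -2.60 from the median of all protein-coding genes. Neither the trend on summed exon length, GC content nor library scaling alone therefore accounts for the ribosomal part there. Length may account for the step from -2.46 to -1.86. The offset used summed exon length and none was fitted on transcript length, so that an effect of transcript length is not excluded. The oxidative phosphorylation median moved from -2.28 (quartiles -2.77 and -1.45; 28 of 73 depleted) to -1.55 (quartiles -2.14 and -0.67; 10) with the length offset and to -2.52 (27) with the GC offset, so that length stays open for these genes and GC content alone does not account for them. In the Ythdf2 IP the length offset with the block moved the 2 medians from -2.49 (quartiles -3.17 and -1.69) to -2.004 (quartiles -2.50 and -1.13) and from -2.05 (quartiles -2.86 and -1.43) to -1.36 (quartiles -2.01 and -0.74), and the depleted genes from 25 to 4 and from 8 to 1, as the folds shrank. A low affinity of the readers for ribosomal protein transcripts is a hypothesis, and unspecific loss of such transcripts in any IP stays open, since no library with an unrelated antibody is among the samples.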

How the results depend on the processing

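The GC offset alone and with the replicate block, limma voom with library weights, the fits of the 6 libraries of a tissue, and leaving out cortex input replicate 1 where a comparison does not contain it were chosen after seeing the data. The cause of the changes below was not tested, except where the fit holds fewer libraries or genes.

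Genes named from the model of all libraries kept their direction wherever it was called. Genes named for a comparison only without the library labelled cortex input replicate 1, such as Apc2 and Snrpf, are not among these values. Of 5146 values for 237 genes and comparisons, 3695 stayed on their side of the threshold, 1277 fell short of it and 80 passed it. Of called values 0 reversed, while 94 values that were called in neither fit changed sign. Of 336 other values, 133 stayed within 1.5 times the reported count (or 0.1 for a correlation) and 203 did not. A test against a fold of 1.2 and leaving out mitochondrial and ribosomal RNA genes changed none of the counts by more than that.

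The enriched and depleted genes are given as cortex Ythdf1, cortex Ythdf2, retina Ythdf1 and retina Ythdf2, and counts without a mention stayed within 1.5 times. DESeq2 size factors gave 2 enriched genes in cortex Ythdf1 and 5 tissue differences with Ythdf1. Library totals gave 2 enriched and 3 depleted genes in cortex Ythdf1, 2 depleted in cortex Ythdf2, 0 and 0 in retina Ythdf1, 0 and 2 in retina Ythdf2, 0 and 0 tissue differences, and 359 differences of the inputs. With no filter the counts were 228 and 880, 310 and 1056, for retina Ythdf2 129 and 723, between antibodies 43 in cortex and 227 in retina, between tissues 1008 and 637, and between inputs 2622. At least 5 CPM in 2 libraries gave 2 enriched in cortex Ythdf1, 92 and 184 in cortex Ythdf2, 121 and 500 in retina Ythdf2, 18 between the retina antibodies and 55 between tissues with Ythdf1.

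DESeq2's Wald test gave 436 and 912, 753 and 1461, 1469 and 2114, and 522 and 1057, with 72 and 663 between antibodies, 1149 and 451 between tissues, and 3415 between inputs. Limma-trend on log2(FPKM + 1) gave 0 enriched in cortex Ythdf1, 15 and 5 in cortex Ythdf2, 0 and 46 in retina Ythdf1, 2 and 33 in retina Ythdf2, 3 between the cortex antibodies, 0 and 0 between tissues, and 74 between inputs. With a pseudocount of 0.1 these were 0, 4 and 2, 0 and 32, 0 and 19, with 0 and 2 between tissues and 80 between inputs. With no filter on FPKM they were 0, 432 and 31, 0 and 40, 6 and 32, with 207 between the cortex antibodies, 0 and 28 between tissues, and 125 between inputs.

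The replicate block gave 1 enriched in cortex Ythdf2, 187 and 487 in retina Ythdf1, 7 and 176 in retina Ythdf2, and 0 and 2 between tissues. For the inputs it gave 403 higher and 404 lower in retina, which are not among the 336 values. Only the groups of the comparison gave 0 enriched in each cortex IP, 2215 and 2269, 499 and 1362, then 116 and 4945 between antibodies, and 0, 0 and 0 between tissues and inputs. The gene length offset gave 3 enriched in cortex Ythdf1, 1 depleted in cortex Ythdf2, 30 and 117 in retina Ythdf2, and 2 between tissues with Ythdf2. With the block it gave 2 depleted in cortex Ythdf2, 175 and 409, 2 and 22, and 0 and 1 between tissues.

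The GC offset gave 2 and 1 in cortex Ythdf1, 1 depleted in cortex Ythdf2, 159 enriched in retina Ythdf2, and 10 and 1 between tissues. With the block it gave 1 enriched in cortex Ythdf2, 250 and 523 in retina Ythdf1, 184 depleted in retina Ythdf2, and 0 and 0 between tissues. Voom with library weights gave 0 and 1, 0 enriched in cortex Ythdf2, 2422 and 2877, 880 and 1494, with 90 and 4652 between antibodies, 11 between tissues with Ythdf1, and 238 between inputs. The 6 libraries of a tissue gave 0 enriched in each cortex IP, 2492 and 2920, 1374 and 1536, and 1313 between the retina antibodies. With the block these were 0 and 0, 2536 and 2846, 1453 and 1519, and 1448.

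Leaving out a library leaves a group with 1, which is assumed to vary like the other groups. Over the libraries of a comparison and cortex input replicate 1, the ranges were 1 to 2796 enriched and 0 to 2215 depleted in cortex Ythdf1, 1 to 3250 and 0 to 2371 in cortex Ythdf2, 0 to 2778 and 0 to 2727 in retina Ythdf1, and 0 to 1180 and 0 to 1550 in retina Ythdf2. They were 0 to 143 and 0 to 1220 between antibodies, 0 to 5103 and 0 to 4315 between tissues, and 135 to 5779 between inputs. Each upper end came from leaving out a cortex input. Cortex input replicate 2 is in no comparison of the retina IPs with their input or with each other, and these ranges leave it out there. Without it the depleted genes of both retina IPs and the genes between the retina antibodies exceeded the upper ends above. The enriched genes of both retina IPs did not.

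The lists with a camera adjusted p under 0.05 numbered 14, 20, 14 and 14 in the 4 IPs, and 0, 0, 0 and 0 with the estimated correlation, 9 and 9 in the retina IPs with the gene length offset, and 10, 17, 15 and 17 without cortex input replicate 1. Correlations over genes with a mean of at least 5 CPM were 0.784 between the retina antibodies and 0.281 and 0.39 across tissues, and in the libraries of a tissue alone 0.69, 0.203 and 0.28. Leaving out cortex input replicate 1 gave 0.582, 0.703, 0.17 and 0.17.

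Library totals in place of TMM put the median log2 value of all genes at -0.58 in cortex Ythdf1, 0.72 in cortex Ythdf2, 0.13 in retina Ythdf2, -1.33 between the cortex antibodies, 0.58 and -0.57 between tissues and -1.17 between inputs. Log2(FPKM + 1) put it at 0.54 in cortex Ythdf2, -0.62 between the cortex antibodies and -0.55 between tissues with Ythdf2, and with a pseudocount of 0.1 these were 1.36, -1.16 and -1.31. Changes in the report are relative to the TMM scaling, and the median of the ribosomal list stayed below 0 in both retina IPs with each length and GC offset. Depth limits the library labelled cortex input replicate 1 most, where 3 counts equal 0.356 CPM.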

Other observations

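The test of the transcript features was written before the values were seen, and the values without the library labelled cortex input replicate 1 were chosen afterwards.

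Whether transcript features track recovery was asked over 14167 of the 14199 protein-coding genes tested, with a bound of 0.1 on Spearman's rho in the same direction in all 4 IP against input comparisons. Transcript length gave rho of 0.0466 and 0.207 in cortex and 0.323 and 0.43 in retina for Ythdf1 and Ythdf2, so that the cortex Ythdf1 IP fell under the bound. GC content gave 0.184, 0.114, 0.341 and 0.0764, with the retina Ythdf2 IP under it. The density of DRACH motifs, the sequence in which m6A is placed, was weakest at -0.0254 and at most -0.0666 in size (-0.136 in the cortex Ythdf1 IP without the library labelled cortex input replicate 1), which is opposite in sign to what a gain of motif-dense transcripts would give. GC content and motif density therefore did not track recovery in all 4 comparisons by the bound set. Length is left open: without that library it gave 0.126 and 0.297 in cortex and 0.317 and 0.419 in retina, above the bound in all 4, and the value under the bound rests in part on that library, whose profile is not that of its label. A motif count over the whole transcript is not a measure of methylation, which these data do not hold.

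Gm47311 had 1 count in 11 libraries and 1943 counts in cortex input replicate 2, and no cause was tested.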
